A study of Danio rerio with 2 samples.

How the data were processed

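Whole cells from dissected heads with eyes of zebrafish at 4 days post-fertilisation had been dissociated, strained and loaded for 10x Genomics single cell 3' sequencing, per the labels' protocols, with 1 library from wild-type animals and 1 library labelled med22 knockout. The number of animals per library, the site of the edits, the way the edits were made and the time of collection are not given in the sources used here. The protocol names a kit for labelling cells with multiplexing oligos, but the matrices hold only genes, so no split of a library by animal or pool was used. The deposited values were whole-number UMI counts per gene and barcode, made with Cell Ranger 6.1.2 on genome build GRCz11, per the file headers and the submitters' processing notes; the annotation release and the cell calling settings are not given in the sources used here. Both matrices held the same 25432 genes, and gene names were those the files pair with the gene identifiers; 699 symbols were shared by more than 1 identifier.

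Depth was measured before any comparison. The wild-type library held 26388 barcodes and 73868567 UMIs (median 1608 UMIs per barcode), and the library labelled knockout 27088 barcodes and 70588157 UMIs (median 1259). The totals per barcode had a narrow mode at 1603 and 1216 UMIs, and the barcodes around it differed little from their pooled profile: the median z of their deviance from it was 1.53 and 1.84, against 116 and 79.4 for barcodes 3000 to 6000 UMIs above the mode. They were treated as background droplets. The filter written before the data were examined asked for at least 200 detected genes and at most 20% mitochondrial UMIs and would have kept them. A step was therefore added after the totals had been seen: a cell needed at least 3000 UMIs more than the mode of its library. It left 999 and 1509 barcodes, the planned filters left 950 and 1456, and Scrublet in scanpy 1.11.5, run per library at an expected rate of 0.8% per 1000 barcodes with its automatic threshold, removed 3 and 2 as doublets. Doublets were expected at 0.76% and 1.16%. If each kept cell carried as many background UMIs as the modal droplet of its library, background RNA would be 4.97% and 5.01% of the UMIs of kept cells. By class this was 2.93% and 2.53% in periderm-like, 6.95% and 6.50% in retina-like, 11.1% and 11.2% in neuron- and glia-like, 13.2% and 11.9% in mesenchyme- and cartilage-like and 16.4% and 14.3% in lens-like cells.

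Kept cells of both libraries were clustered together on 2000 variable genes and 40 principal components with 15 neighbours and Leiden resolution 2 (igraph 0.11.9), which gave 39 clusters. A cluster was named from cell type markers fixed before the data were examined, with limits set afterwards: at least 3 of a type's markers had to be among the 100 leading genes of the cluster, or 5 where no marker of its class was among the first 10. A name was refused where another class had more markers among those 10. Names are given as "-like", and no annotation by the submitters was used. Clusters were joined into classes, and classes with at least 100 cells in each library (periderm-, neuron- and glia-, and retina-like) were compared gene by gene; 7 classes had at least 30 cells in each library.

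UMIs were summed over the cells of a library or class and scaled to the total (CPM). With 1 library per group there is no test: ratios carry exact conditional (Clopper-Pearson) intervals, single values exact Poisson intervals and shares exact binomial (Clopper-Pearson) intervals, all at 95%, all for counting error only. A gene at 0 was set to a floor of 3 UMIs for a bound on its fold. A gene list was described by the median log2 ratio of its members with at least 20 UMIs, by the numbers higher and lower, and by the central 95% of 10000 random lists of the same size drawn from 20 bins of mean expression; this range describes the 2 libraries and tests nothing about the genotype. The 34 lists were fixed before the data were examined, and 1 of them is not reported here. Members were matched by symbol or, for 7 genes, by a synonym. Shares of cells with proliferation UMIs were taken after thinning each cell to 500 UMIs. Counts were simulated with Poisson error only and with genes independent of each other. On these, 95.7% of the intervals of 18586 unchanged genes held the true ratio. Of 100 genes changed 1.5-fold, 94% had an interval on the true side of 0. Real counts also vary between cells, so these figures check the computation and do not carry over to these data. Of simulated lists of 25 unchanged genes 8% lay outside the central 95%, so a list just outside its range carries little weight.

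Genes were named by a rule fixed before the data were examined. A gene needed at least 50 UMIs and 20 CPM in the higher library (50 CPM within a class), and genes were ranked by the interval bound nearest 0. The first 10 higher and 10 lower genes were named over the whole library. Within a class the first 3 in each direction were named, among genes at or above their median level over classes. Over classes the 12 highest and 12 lowest medians were named, among genes measured in at least 2 of the 3 compared classes. Their highest class CPM could be at most 10 times their median class CPM in each library. Of a described list up to 4 members were named, 3 by rank and the most abundant, and med22 and other Mediator subunits were named by choice. Because single cells held most UMIs of many of these genes, a second ranking was added after they had been seen, limited to genes in which no cell held more than 10% of the UMIs of the higher library. Genes within classes are described for the 3 compared classes, and a few of other classes among the other observations, although the rule allowed more; this was decided after the data were seen. Differences between classes are listed only where both medians exceed 0.2 in size and lie outside the central 95% of random lists, limits set after the data were seen. Genes with clone-type names were ranked but are mostly not described.

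Alternatives fixed before the data were examined covered the cell filter, doublets, clustering resolution, a neighbour graph balanced between libraries, TMM factors (edgeR 4.0.16 in R 4.3.3), totals without abundant tissue genes, thinning, equal class weights and list members with at least 100 UMIs. Alternatives for the background step, an upper limit on UMIs, subtraction of the background profile, leaving out the top cell of each gene and smaller classes were chosen after seeing the data. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.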

Results

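Cells from heads with eyes of zebrafish (Danio rerio) at 4 days post-fertilisation were profiled by droplet RNA sequencing, with 1 library from wild-type animals and 1 library labelled med22 knockout. The series title labels the knockout F0, the injected generation, in which edits usually differ between cells. med22 encodes a subunit of the head module of Mediator, the complex that connects transcription factors with RNA polymerase II. The comparison addressed which cell types and genes of the head differed between the library labelled knockout and the wild-type library. The wild-type matrix held 26388 barcodes with 73868567 unique molecular identifiers (UMIs), and the matrix labelled knockout held 27088 barcodes with 70588157 UMIs. Most barcodes were background droplets with free RNA: 18818 wild-type barcodes (71.3%) and 17450 barcodes of the other library (64.4%) lay within 0.15 times the modal total on either side of it, which was 1603 and 1216 UMIs. After the background step and the cell filters, 947 wild-type cells with 30545313 UMIs and 1454 cells of the library labelled knockout with 35280131 UMIs were kept. The median cell held 17962 UMIs and 3430 genes in the wild-type library, against 11632 UMIs and 2858.5 genes in the library labelled knockout. With 1 library per group no difference has a replicate check and no test was made. Values in parentheses after a ratio are 95% intervals, and they cover counting error only. All log2 ratios are of the library labelled knockout over the wild-type library.

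med22 (ENSDARG00000014148) was not lower in the library labelled knockout. It was counted at 7.50 CPM (UMIs scaled to the library total; 229 UMIs, exact Poisson interval 6.56 to 8.53) in wild-type cells and at 8.39 CPM (296 UMIs, 7.46 to 9.40) in the library labelled knockout, a log2 ratio of 0.16 (-0.09 to 0.42). Within classes, the log2 ratio was -0.13 (-0.51 to 0.24) in periderm-like cells, 0.81 (-0.29 to 2.06) in neuron- and glia-like cells and -0.38 (-2.10 to 1.18) in retina-like cells, so no difference was detectable at this depth in these 3 classes. Over 31 measured Mediator subunits the median log2 ratio was -0.10, with 22 lower and 9 higher, below the central 95% of random lists matched on expression (-0.03 to 0.20); with background droplets kept as cells it was 0.03. Among them, med21, which joins the middle module of Mediator, was counted at 33.9 and 27.8 CPM (log2 -0.29, -0.42 to -0.16). med31, a middle subunit, had a log2 ratio of -0.25 (-0.35 to -0.15), whereas the head subunit med30 was higher, at 9.36 and 13.0 CPM (0.47, 0.26 to 0.69). The list median was -0.13 in periderm-like cells, -0.29 in retina-like cells and 0.13 in neuron- and glia-like cells. In retina-like cells med19a had a log2 ratio of -0.71 (-0.99 to -0.45). A 3' tag does not show whether the coding sequence was edited, so these counts do not check the genotype, which is carried below as a label.

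Periderm-like and retina-like cells made up a smaller part of the library labelled knockout, and neuron- and glia-like, mesenchyme- and cartilage-like and red blood cell-like cells a larger part. Periderm-like cells, which form the outer layer of larval skin, were 31.8% of wild-type cells (301 of 947; exact binomial interval 28.8 to 34.9) and 21.3% of cells labelled knockout (310 of 1454), a log2 ratio of -0.58 (-0.81 to -0.34). Neuron- and glia-like cells were 11.2% (106 cells; 9.26 to 13.4) against 19.7% (286 cells; 17.7 to 21.8), 1.76-fold (1.40 to 2.22) higher in the library labelled knockout. Mesenchyme- and cartilage-like cells were 9.08% (86 cells) against 15.7% (229 cells), a log2 ratio of 0.79 (0.43 to 1.17). Retina-like cells were 13.5% (128 cells; 11.4 to 15.9) against 7.70% (112 cells; 6.38 to 9.20), a log2 ratio of -0.81 (-1.19 to -0.43). The background droplets of the library labelled knockout held more phototransduction RNA (1.32% of UMIs, against 0.284% in the wild-type library). The shares of kept cells therefore do not show how many retinal cells each suspension held. Red blood cell-like cells numbered 9 and 43 (log2 1.64, 0.58 to 2.86), and macrophage- and microglia-like cells 15 and 43 (0.90, 0.02 to 1.86). Mucous cell-like cells were 2.75% and 1.38% (26 and 20 cells; interval of the log2 ratio -1.91 to -0.10). The shares of basal epidermis-like (0.11, -0.29 to 0.52), ionocyte-like (0.08, -0.58 to 0.76), lens-like (0.06, -0.53 to 0.67), muscle-like (-0.62, -1.43 to 0.19), gut- and liver-like (-0.92, -1.94 to 0.07) and endothelium-like cells (0.66, -0.68 to 2.17) differed by no more than counting error. Clusters that stayed unnamed held 6.76% and 6.46% of the cells, among them a cluster led by pou2f3, trpm5 and avil.

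Within these classes, bipolar cell-like cells were 7.29% of wild-type cells and 3.16% of cells labelled knockout (69 and 46 cells; log2 -1.20, -1.77 to -0.64), and rod-like cells 3.38% and 1.51% (32 and 22; -1.16, -2.01 to -0.33). The rod-like cluster had as many photoreceptor precursor markers as rod markers (5) among its 100 leading genes, with crx, neurod4 and insm1a among the first 10. Cone-like cells went the other way, at 0.528% and 1.65% (5 and 24; 1.64, 0.23 to 3.39). Mature neuron-like cells were 4.01% and 8.18% (38 and 119; 1.03, 0.49 to 1.60), and newborn neuron-like cells, an olfactory-type cluster of 17 and 32 among them, 4.44% and 7.29% (42 and 106; 0.72, 0.19 to 1.27). Fibroblast- and mesenchyme-like cells were 5.91% and 10.9% (56 and 159; 0.89, 0.44 to 1.35). Cells needed at least 3000 UMIs above the modal total, and periderm-like cells held a median of 46897 and 38325.5 UMIs, against 10626.5 and 8316 in neuron- and glia-like cells. From 6000 UMIs above the modal total the log2 ratio was -0.62 for the periderm-like and 0.44 for the neuron- and glia-like share, from 10000 UMIs -0.45 and 0.42, and from 3 times the modal total -0.81 and 0.71. With the 900 barcodes of most UMIs kept in each library, the log2 ratio was -0.22 (-0.48 to 0.04) for the periderm-like share and 0.26 (-0.11 to 0.64) for the neuron- and glia-like share.

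**Figure D1:**
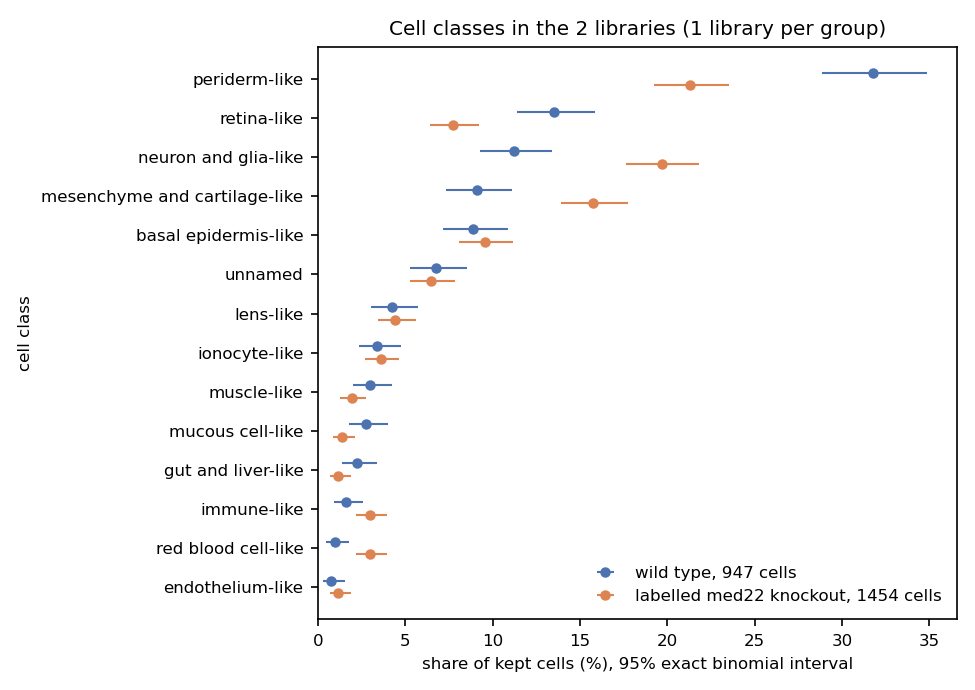
Share of kept cells (percent) in each cell class, with 1 point per library (wild type, and the library labelled med22 knockout) and bars for the exact 95% binomial interval, counting error only. The periderm-like share was 31.8% and 21.3%, and the neuron- and glia-like share 11.2% and 19.7%.

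fkbp5, klf2a, lpin1 and hsd11b2 were higher over all cells of the library labelled knockout, and tnfb was lower, with no single cell above 10% of the UMIs of the higher library. fkbp5, a co-chaperone of the glucocorticoid receptor that the receptor itself induces, was counted at 20.0 and 103 CPM (log2 2.36, 2.24 to 2.49). Its log2 ratio was above 0 in each of the 7 classes with at least 30 cells per library, from 0.53 in lens-like cells, where each library held fewer than 20 of its UMIs, and 1.87 in mesenchyme- and cartilage-like cells to 4.30 in retina-like cells; it was also higher in the background droplets (2.22). klf2a, a transcription factor induced by blood flow and by stress, was counted at 462 and 2784 UMIs (2.38, 2.24 to 2.53). lpin1, a phosphatidate phosphatase of lipid synthesis, was counted at 390 and 1959 UMIs (2.12, 1.96 to 2.28). hsd11b2, which inactivates cortisol, was counted at 21.7 and 83.3 CPM (1.94, 1.82 to 2.06); it is among the 15 leading genes of a mural cell-type mesenchyme cluster. The microtubule-binding gene tppp3 was counted at 7.01 and 39.3 CPM (2.49, 2.28 to 2.70). tnfb, a cytokine of the tumour necrosis factor family, was counted at 26.7 and 5.67 CPM (-2.23, -2.47 to -2.01), and the cytochrome P450 gene cyp2y3 had a log2 ratio of -1.55 (-1.72 to -1.37). Several of these ratios depend on the make-up of the library: with classes weighted equally klf2a was 1.16, lpin1 1.74, hsd11b2 1.27, tppp3 1.26, tnfb -0.75 and cyp2y3 -0.38.

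Several further genes lead single clusters. The globin hbbe2 (log2 2.29) belongs to red blood cell-like cells, rbp4 (1.79) and ptgdsb.1 (1.73) lead a basal epidermis-like cluster whose share differed by no more than counting error (34 and 60 cells; log2 0.20, -0.43 to 0.85). plekhs1 (1.91) and urgcp (1.70) lead periderm-like clusters, and plekhs1 was also higher in basal epidermis-like (1.80) and ionocyte-like cells (1.45). On the lower side, gnb3a (-1.77), gng13b (-1.70), bhlhe23 (-1.36), isl1 (-1.25) and vsx1 (-1.23) lead the bipolar cell-like cluster, and aep1 (-1.73) leads a periderm-like cluster.

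Ranked with no limit on single cells, the first genes came mostly from a few cells of rare types. Among kept cells, glucagon genes were found almost only in the wild-type library, with gcgb at 2573 and 9 UMIs (log2 -8.37, -9.50 to -7.44) and gcga at 2330 and 27 UMIs (-6.64, -7.24 to -6.09). The difference was smaller in the background droplets, where gcgb had a log2 ratio of -2.11 and gcga of -1.56. The pancreatic enzyme genes ctrb1 (-4.30), prss59.2 (-4.16), cela1.6 (-3.94), pdia2 (-3.91) and prss1 (-2.91) were also lower, and 1 cell held from 45.9% to 56.7% of their wild-type UMIs. The iridophore gene pnp4a (-3.82), the defensin gene defbl1 (-3.51) and apoda.2 (-3.68) were lower in the same way, with 80.6% of the wild-type defbl1 UMIs in 1 cell. On the higher side, 1 cell held 97.0% of urp1 UMIs, 99.1% of ins UMIs, 86.3% of matn1 UMIs and nearly all rcvrnb UMIs, and without the top cell of each library the ratios of ins and rcvrnb were 0.13 and -0.35. The neuropeptide gene galn (6.21, 5.43 to 7.12) had 1074 of its 1110 UMIs in 2 cells, and the green cone opsin gene opn1mw2 (5.33, 4.81 to 5.91) had 48.1% in 1 cell. For ly6m2 (10 and 790 UMIs) and the apolipoprotein gene apoc1 (3.45, 3.22 to 3.68), a macrophage marker here, 1 cell held 37.3% and 26.3%. otos (4.84) and epd (3.90) lead a cartilage-like cluster.

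In periderm-like cells, klf2a and fkbp5 were higher in the library labelled knockout, tnfb and adh8b were lower, and mitotic genes were lower. klf2a was counted at 9.46 CPM (156 UMIs) and 120.5 CPM (1797 UMIs), 12.7-fold higher (log2 3.67, 3.43 to 3.92). fkbp5 was counted at 24.1 and 126 CPM (2.39, 2.23 to 2.55), and tppp3 at 4.67 and 55.7 CPM (3.58, 3.24 to 3.93). adh8b, an alcohol dehydrogenase, was counted at 73.9 and 24.8 CPM (-1.58, -1.75 to -1.41). tnfb was counted at 45.0 and 6.97 CPM (-2.69, -3.00 to -2.39), while socs3b, which limits cytokine signalling through stat3, was counted at 247 and 1010 UMIs (2.18, 1.97 to 2.38). Chaperones of the endoplasmic reticulum were higher, with hspa5 at 154 and 486 CPM (1.66, 1.59 to 1.72) and hsp90b1 at 165 and 450.4 CPM (1.45, 1.39 to 1.52). The unfolded protein response list had a median of 0.60 (random lists -0.09 to 0.17) with 17 members higher and 5 lower. Some clusters of the class differed in their cells: a cluster led by irg1l and urgcp held 34 wild-type and 82 knockout-labelled cells and a cluster led by plekhs1 held 11 and 41, whereas a cluster led by aep1 held 84 and 52 and a dividing cluster 45 and 15. The remaining 3 held 33 and 22, 70 and 74, and 24 and 24. Over the class plekhs1 had a log2 ratio of 2.19 and aep1 of -1.56; the high ratio of agr2 (2.73) came from 1 cell with 90.6% of its UMIs.

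In neuron- and glia-like cells, DNA replication genes, Notch signalling genes and splicing factors were higher in the library labelled knockout. The S phase list had a median log2 ratio of 0.84 (random lists 0.00 to 0.37) with 28 members higher and none lower, including pcna, the sliding clamp of replication, at 192 and 365 CPM (0.92, 0.74 to 1.11), slbp and uhrf1 (2.36-fold). The share of cells with at least 2 S phase UMIs after thinning differed by no more than counting error (13 of 106 and 38 of 286 cells; 0.12, -0.82 to 1.15). The Notch list had a median of 0.44 (random lists -0.01 to 0.38), with the Notch effectors her2 (3.35, 2.48 to 4.37), her15.1 (1.55, 1.16 to 1.95) and her4.1 (0.70, 0.39 to 1.02) higher. The splicing list had a median of 0.28 with 35 members higher and 9 lower, including the spliceosome helicase snrnp200 (0.90, 0.63 to 1.18) and eftud2 (2.15-fold). pax7a was counted at 13 and 184 UMIs (2.80, 1.99 to 3.73) and the histone gene hist1h4l at 17.7 and 60.4 CPM (1.78, 1.19 to 2.41). galn was counted at 1 and 1081 UMIs (9.05, 6.57 to 14.36), with 70.9% of the UMIs in 1 cell. urp1, at 0 and 711 UMIs, was at least 116-fold higher, and the odorant receptor genes or132-5, at 227 and 0 UMIs, and or128-3, at 102 and 0 UMIs, were at least 154-fold and at least 69.2-fold lower (floor of 3 UMIs), each with over 99% of UMIs in 1 cell; so was the cocaine- and amphetamine-regulated transcript gene cart4 (-7.36, -9.65 to -5.79). rho (2.81) and crystallins such as crygm2d9 (-0.98) mirrored the background droplets (2.35 and -1.03). By cluster, that of mature GABA-type neurons led by sv2a and gad2 held 27 and 107 cells, a radial glia-like cluster 26 and 61, a newborn neuron-like cluster 25 and 74, an olfactory-type cluster led by ompb and s100z 17 and 32, and a second mature neuron-like cluster, led by phox2bb, 11 and 12.

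In retina-like cells, glycolytic genes, GABA-related genes and immediate early and dissociation response genes were higher in the library labelled knockout, and endoplasmic reticulum chaperones were lower. The make-up of the class differed, with 69 and 46 bipolar cell-like, 32 and 22 rod-like and 5 and 24 cone-like cells, and the median cell held 2.39% and 3.75% mitochondrial UMIs. The fibrillar collagen list was also higher (1.97; 17 members higher, 1 lower). The glycolysis and hypoxia list had a median log2 ratio of 0.74 with 24 members higher and 2 lower, with aldocb at 241 and 742 CPM (3.09-fold) and eno1a at 289 and 745 CPM (2.58-fold). The GABA list had a median of 0.80 with 16 members higher and 2 lower, including the chloride exporter gene slc12a5b (1.73, 1.44 to 2.03). The immediate early list had a median of 0.94 with 15 members higher and 4 lower: egr4 was counted at 15.9 and 139 CPM (3.13, 2.68 to 3.60), whereas junba was lower (-2.30, -2.69 to -1.94). glulb, a glutamine synthetase of Müller glia, was counted at 171 and 465 CPM (1.44, 1.28 to 1.60), with gabrr2a (1.37, 1.03 to 1.70) and cdo1 (1.15, 0.82 to 1.49) also higher; with every deposited barcode entering, these 3 ratios were -0.04, -0.05 and -0.08. slitrk6 was counted at 74.2 and 24.8 CPM (-1.58, -2.05 to -1.14) and nol4la at 57.9 and 14.3 CPM (-2.02, -2.63 to -1.45). hspa5 was counted at 286 and 134 CPM (-1.10, -1.30 to -0.90), and the unfolded protein response list had a median of -0.69 (random lists -0.32 to 0.15). This difference was not separated from cells of other types in the class. There muc5.1, which leads the mucous cell-like cluster, was counted at 133 wild-type and 3 knockout-labelled UMIs. opn1mw2 (6.20, 5.65 to 6.82) and the red cone opsin gene opn1lw2 (3.49, 3.42 to 3.55) followed the cone-like cluster, which held 5 and 24 cells, and gng13b (-1.25) the bipolar cell-like cluster, which held 69 and 46. scinla (6.27) and exorh (6.90) each had over 97% of UMIs in 1 cell, and gcga (-9.66) and gcgb (-9.23) had 75.4% and 68.4%. pnoca, at 272 and 0 UMIs, was at least 64.3-fold lower (floor of 3 UMIs), with 87.9% in 1 cell.

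The median log2 ratio of the circadian clock list was above 0 in every class examined, although not all of its members were higher. The clock list had a median log2 ratio of 0.66 over all cells (random lists -0.02 to 0.21; 23 members higher, 11 lower), 0.70 in neuron- and glia-like, 0.66 in periderm-like and 1.05 in retina-like cells. It was 0.37 in basal epidermis-like, 0.24 in ionocyte-like, 0.89 in mesenchyme- and cartilage-like and 1.11 in lens-like cells, the last with 7 members and a value of -0.04 when cells needed 500 genes. per1a, a repressor of the clock, was counted at 11.2 and 33.5 CPM over all cells (1.58, 1.41 to 1.76) and at 10.5 and 40.8 CPM in neuron- and glia-like cells (1.96, 1.21 to 2.81). The repressor bhlhe41 was 3.44-fold higher over all cells (105 and 417 UMIs), nr1d1, a nuclear receptor that represses arntl genes, 3.14-fold higher in periderm-like cells (61 and 173 UMIs), and bhlhe40 5.33-fold higher in retina-like cells (316 and 1195 UMIs). By contrast, 5 arntl and clock genes had a median log2 ratio of -0.33 over all cells, with 4 of 5 below the median of all genes.

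**Figure D2:**
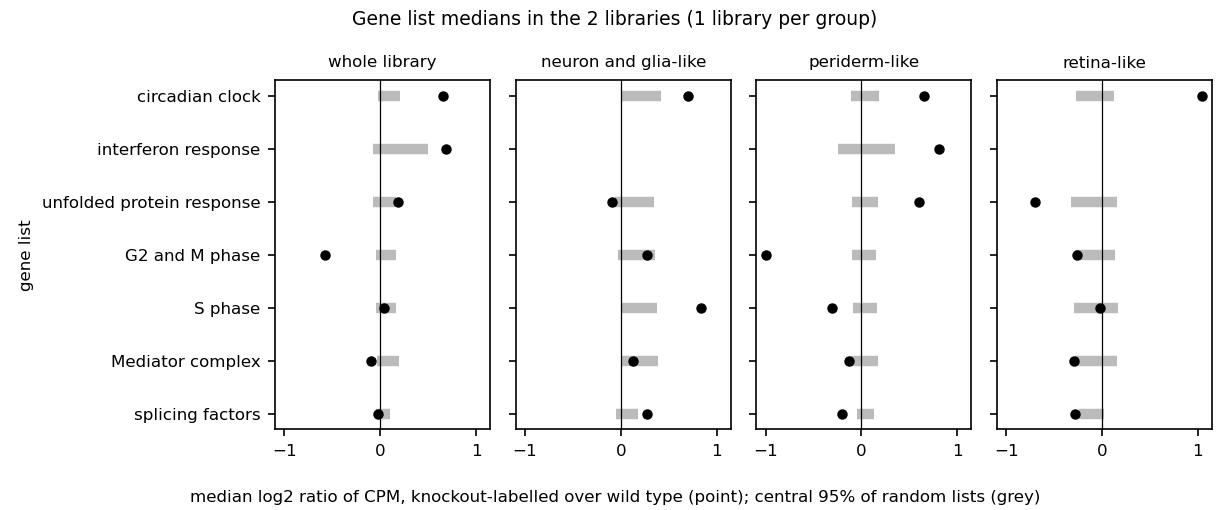
Median log2 ratio (library labelled knockout over wild type) of the members of 7 gene lists over all cells and in the 3 compared classes; each point is 1 median and each grey bar the central 95% of 10000 random lists matched on expression. The circadian clock median was 0.66 over all cells and the G2 and M phase median -1.0 in periderm-like cells.

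Mitotic genes were lower over all cells and in periderm-like cells of the library labelled knockout, but not in every class. The G2 and M phase list had a median log2 ratio of -0.58 over all cells with all 31 measured members lower (random lists -0.04 to 0.16), -1.0 in periderm-like cells, -0.26 in retina-like cells and 0.27 in neuron- and glia-like cells, the last 2 within their random ranges. It was -0.47 in mesenchyme- and cartilage-like cells (5 members higher, 24 lower), -0.20 in basal epidermis-like (6, 24), 0.04 in lens-like (11, 10) and 0.67 in ionocyte-like cells (24, 5). In periderm-like cells mki67, a marker of cycling cells, was counted at 152 and 56.7 CPM (-1.42, -1.54 to -1.31) and top2a at 90.7 and 34.5 CPM (-1.40, -1.54 to -1.25). The dividing periderm-like cluster held 45 wild-type and 15 knockout-labelled cells, with a median of 70691 UMIs. Summed values over periderm-like and over all cells also depend on its cell numbers, and its part in them was not separated. The S phase list had a median of -0.31 in periderm-like cells, 0.04 over all cells and -0.02 in retina-like cells. With each cell thinned to 500 UMIs, 26.6% of wild-type periderm-like cells (80 of 301; 21.7 to 31.9) and 16.5% of those labelled knockout (51 of 310; 12.5 to 21.1) had at least 2 G2 and M phase UMIs (-0.69, -1.23 to -0.17). The log2 ratio of these shares was -0.31 (-0.71 to 0.10) after thinning to 1000 UMIs and -0.32 (-0.67 to 0.04) with at least 1 such UMI at 500. Over all cells the shares were 31.0% and 25.4% (-0.29, -0.52 to -0.06), but the ratio was within counting error after thinning to 1000 UMIs (-0.10, -0.27 to 0.08) and with at least 1 such UMI (-0.11, -0.27 to 0.05). At 2 UMIs of 500 the shares were 43.0% and 32.1% in retina-like cells and 25.5% and 29.7% in neuron- and glia-like cells. With at least 2 S phase UMIs, there were 143 of 947 wild-type cells and 218 of 1454 cells labelled knockout. Background droplets, thinned alike, gave 18.0% and 19.7% for G2 and M phase and 5.07% and 6.13% for S phase, so a periderm-like share of 16.5% was no higher than that of the droplets. Background RNA was estimated at only 2.53% of the UMIs of knockout-labelled periderm-like cells. The share among droplets is therefore not the background level of these cells. No cell was too shallow to thin, and the unthinned G2 and M phase shares over all cells were 98.2% and 97.0%.

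Cartilage, stromal, blood and neural lists were higher over all cells, as the shares of their classes were. The cartilage matrix list had a median log2 ratio of 1.70 (19 members higher, 5 lower), the fibrillar collagen list 0.77 (22, 4), and the globin list 1.28 (9, 0), with hbbe1.1 at 958 and 2740 CPM (1.52). Within mesenchyme- and cartilage-like cells the cartilage list had a median of 1.28, and col2a1a, the main cartilage collagen, was counted at 754 and 3088 CPM (2.03, 1.93 to 2.14); cartilage-like cells were 30 of the 86 wild-type and 70 of the 229 knockout-labelled cells of the class. The GABA list had a median of 0.74 (22, 3), the glutamate list 0.66 (25, 5) and the synaptic vesicle list 0.64 (26, 5); within neuron- and glia-like cells the synaptic median was 0.44 (random lists -0.08 to 0.22), the glutamate median 0.44, only just above its range (0.01 to 0.43), and the GABA median 0.31, inside its range (-0.07 to 0.35). The synaptic list was higher still in some other classes, at 1.0 in periderm-like, 0.89 in basal epidermis-like and 1.83 in mesenchyme- and cartilage-like cells (but -2.08 in ionocyte-like cells, with 6 members), and in the background droplets (1.19; 31, 0). The phototransduction list had a median of 0.58 (40, 9) and the crystallin list -0.44 (6, 38), and both differed in the same direction in the background droplets. The lipid transport list had a median of 0.62 (15, 6), with apoa2 at 40.6 and 135 CPM (1.73, 1.64 to 1.82), and the inflammation list 0.58 (18, 8), with ccl34b.1, a macrophage chemokine, at 2.15 (1.98 to 2.32). The interferon list had a median of 0.68 (13, 1) over all cells and 0.81 in periderm-like cells, where the interferon-induced factor irf1b was counted at 3.70 and 10.5 CPM (1.51, 1.07 to 1.96). mxc, an antiviral gene, had a log2 ratio of 2.94 (2.44 to 3.47) over all cells.

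The remaining lists differed less over all cells. The median log2 ratio of all measured genes was 0.12, and with TMM factors it was 0.01. Against it, glycolysis had a median of 0.37 (38 members higher, 1 lower), the mitochondrial genome 0.25 (13, 0), the unfolded protein response 0.18 (15, 7), nuclear oxidative phosphorylation genes 0.11 (72, 7) and cytosolic ribosomal proteins 0.08 (75, 5), all above their random ranges; with TMM factors the last 2 were 0.00 and -0.03. Cholesterol synthesis (-0.14; 6, 20), skeletal muscle contraction (-0.18; 13, 22) and the proteasome (-0.07; 6, 31) lay below theirs. The muscle list was higher within neuron- and glia-like (0.75), periderm-like (0.43), retina-like (0.21) and mesenchyme- and cartilage-like cells (0.67), and over all cells it was 0.028 without the top cell of each gene. It was also higher in the background droplets (0.52; 32, 3). Medians within the random ranges were found for canonical Wnt targets (0.33), myelin genes (0.34), Notch signalling (0.20), retinoic acid response (0.10), apoptosis (0.07), RNA polymerase II and general factors (0.06), heat shock (0.06), translation factors (0.05), immediate early genes (0.00) and splicing factors (-0.02). Among the polymerase genes, polr2a, the largest subunit of RNA polymerase II, was counted at 82.7 and 148 CPM (0.84, 0.77 to 0.91).

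Across the 3 compared classes, genes were ranked by their median log2 ratio, with their highest class level limited relative to their median class level. Genes nearly absent from 1 class could pass this limit, such as aldoca with 0 and 1 UMIs in periderm-like cells. Most of the named genes were measured in only 2 classes, and for several of them 1 cell held most UMIs of a class. aldoca, an aldolase of Purkinje cells, had the highest median log2 ratio (6.09), with 3 and 250 UMIs in neuron- and glia-like and 1 and 80 in retina-like cells, 96.3% of 1 count in 1 cell. gmnc (3.84), foxa (3.41), slc24a3 (3.02), ccka (2.98), apoa4b.1 (2.78), cxl34b.11 (2.78) and aqp3a (2.78) followed; cxl34b.11 and aqp3a lead basal epidermis-like clusters. On the lower side were the mucin genes muc5.1 (-3.13) and muc5.2 (-2.36), which lead the mucous cell-like cluster, scxa (-2.56), tmsb5 (-2.50), fabp11b (-2.41), pax10 (-2.14), hoxb1b (-2.07), bmp5 (-2.03), hpdb (-2.02) and calb2a (-1.96); hpdb and calb2a lead other clusters. Not every class went the same way: calb2a was higher in neuron- and glia-like cells (312 and 766 UMIs; 0.27, 0.08 to 0.47) and bmp5 in periderm-like cells (5 and 18 UMIs; 1.99, 0.51 to 3.78). fabp11b, a fatty acid-binding protein, was counted at 41 and 7 UMIs in periderm-like and 30 and 4 in retina-like cells, and no cell held more than 7.32% of either.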

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

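The comparison of 900 barcodes in each library, the subtraction of the background profile, the removal of top cells and the tests for lysed neurons and time of day were chosen only after the results were seen.

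In 4 lists the medians of 2 compared classes had opposite directions, each over 0.2 in size and outside the central 95% of random lists; these differences between classes were not tested. The S phase list was higher in neuron- and glia-like cells of the library labelled knockout (log2 0.84, 28 members higher and 0 lower) and lower in periderm-like cells (-0.31, 1 and 27). The unfolded protein response list was higher in periderm-like cells (0.60, 17 and 5) and lower in retina-like cells (-0.69, 4 and 15), with the chaperone gene hspa5 at 154 and 486 CPM in the former and at 286 and 134 CPM in the latter. The retina-like value was not separated from cells of other types in that class, where the mucin gene muc5.1 was counted at 133 and 3 UMIs. The fibrillar collagen list was higher in retina-like cells (1.97, 17 and 1), with col5a1 at 3.02 and col1a1b at 2.32. It was lower in neuron- and glia-like cells (-0.39, 6 and 13), where fn1a was at -2.65 and sparc at -0.77. The latter median was positive in 14 alternatives, at 0.73 with no doublets removed. The retina-like difference of the collagen list was also not separated from cells of other types in that class. There 1 cell held nearly all UMIs of scinla, which leads a cartilage-like cluster. The splicing list was higher in neuron- and glia-like cells (0.28, 35 and 9) and lower in retina-like cells (-0.28, 3 and 41), with hnrnpaba at -0.74.

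The background droplets, which enter no comparison of cells, held more neural and photoreceptor RNA in the library labelled knockout than in the wild-type library. Phototransduction genes were 1.32% of its background UMIs and 0.284% of those of the wild-type library (4.64-fold). The synaptic vesicle list was at 0.205% and 0.0888% (2.31-fold), the GABA list at 0.0516% and 0.0221% (2.34-fold), and the glutamate list at 0.0377% and 0.0166% (2.28-fold). The circadian clock list was at 0.0597% and 0.0253% (2.36-fold), and the interferon list at 0.00564% and 0.00281% (2.01-fold). Crystallins, at 26.5% and 40.6%, were lower, and the median log2 ratio of all genes in the background was itself 0.50.

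The periderm-like share was lower and the neuron- and glia-like share higher in the library labelled knockout. Lysis of wild-type neurons before capture would raise synaptic RNA among wild-type background droplets. With crystallins left out of the totals, the synaptic list in the background droplets had a log2 ratio of 0.90 (0.88 to 0.92). This argues against such lysis as the whole source. Background RNA also depends on how many neurons each suspension held and on lysis in the other library, so a part is not excluded. Wild-type cells held more UMIs, and a minimum on UMIs could set part of the difference: with 900 barcodes kept in each library the log2 ratio was -0.22 (-0.48 to 0.04) for periderm-like and 0.26 (-0.11 to 0.64) for neuron- and glia-like cells. Both intervals hold 0, but the periderm-like ratio was -0.62 from 6000 UMIs above the mode, -0.45 from 10000 UMIs and -0.81 from 3 times the mode, so this explanation stays open. The genotype of the animals also stays open as untested, because with 1 library per group it cannot be told apart from differences between animals and dissociations.

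The clock list was higher in the library labelled knockout, with a median of 0.79 over the 3 compared classes. Free RNA as the whole source is argued against by a median of 0.76 after the background profile was subtracted. Without the top cell of each gene the median was 0.86, which argues against 1 cell per gene and library but does not exclude several. Both lay above the random range of the main setting (-0.08 to 0.19), which was not recomputed. Leaving out top cells also raised the median of all genes in neuron- and glia-like cells, from 0.20 to 0.32. The gene sets for the test of time of day were chosen after the clock list had been seen to be higher, per1a and nr1d1 among them. Their directions are therefore no independent support. Relative to all genes, the 5 arntl and clock genes had a median of -0.45, with 4 of 5 below, and the 8 period-phase genes a median of 0.92, with 8 of 8 above. This is the pattern a difference in the time of day or light at collection would give, and it may account for the clock genes. It cannot be told apart from an effect of the genotype, which stays open as untested, since collection times are not given in the sources used here.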

How the results depend on the processing

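The alternatives for the background step, the upper limit of 100000 UMIs, the subtraction of the background profile, the removal of top cells and the smaller classes were chosen only after the results were seen; the others were not. Single members of gene lists were not recomputed, only the medians of their lists. Numbers below are log2 ratios unless they are counts, and where no reason is given the cause was not tested.

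Of 182 class shares under an alternative, 160 stayed close, 18 moved and 4 reversed. The neuron- and glia-like share (0.81) was higher in each alternative run, but less so at Leiden resolution 1 (0.43), with a balanced neighbour graph (0.44), from 6000 UMIs above the mode (0.44), from 10000 UMIs (0.42) and with 900 barcodes per library (0.26). The periderm-like share (-0.58) was -1.1 at Leiden resolution 1, -0.87 at resolution 3, -0.22 with 900 barcodes and 0.66 with every deposited barcode. The retina-like share (-0.81) was -1.26 from 6000 UMIs above the mode, 3.28 with every barcode and 2.36 with no background step. With every barcode the mesenchyme- and cartilage-like share (0.79) was -0.64. The lens-like share (0.06) was 0.89 from 3 times the mode, -1.63 with 900 barcodes, -2.12 with every barcode and -2.38 with no background step. The gut- and liver-like share (-0.92) was 0.37 and 2.93 in these last 2 settings. The basal epidermis-like share (0.11) was 0.53 with 900 barcodes. The unnamed share (-0.06) was 0.98 with every barcode and 0.57 from 10000 UMIs. In the 2 settings that keep background droplets, the doublet step removed many barcodes: 11753 of 26388 and 14192 of 27088 stayed with every barcode entering, and 11866 and 14338 with no background step, so these settings say little about cells. Asking for 500 detected genes removed 1 cell, yet periderm-like cells went from 301 and 310 to 257 and 247, so class borders shift with small changes of the input.

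med22 (0.16) was moved in 2 of 64 values and reversed in 0. Of 697 values of genes over all cells, 248 moved and 3 reversed. Weighting classes equally moved 32 of 41 and reversed 1, so most of these ratios depend on the make-up of the library; klf2a (2.38) was then 1.16, tnfb (-2.23) -0.75 and cyp2y3 (-1.55) -0.38, while fkbp5 (2.36) was 2.29. The 3 reversed values came from 2 genes: ins (6.93) was -0.10 with classes weighted equally and -0.073 from 6000 UMIs above the mode, and rcvrnb (4.84) was -0.35 without its top cell. Of 703 values within classes, 234 moved and 23 reversed, mostly of genes held by 1 cell. In neuron- and glia-like cells without the top cell, urp1 was -0.61 and CABZ01030107.1 -2.61, and the latter was -0.69 after thinning to 500 UMIs. Wild-type cells held no urp1 UMIs and were set to the floor of 3 UMIs, so its value is no change of direction. It shows that few urp1 UMIs were left outside the top cell. The CABZ01030107.1 values may come from the floor in the same way. or132-5 was 0.18 from 10000 UMIs. rho (2.81) was -1.02 with the background profile subtracted. In periderm-like cells agr2 (2.73) was -0.42 without its top cell, -0.45 without cells above 100000 UMIs and -0.043 after thinning. The last value arises where both libraries have the same count or both are at the floor, so it shows no change of direction. si:dkey-33i11.4 (-3.05) was 1.40 with every barcode, 0.42 from 3 times the mode, 0.60 from 6000 UMIs above it, 0.45 without cells above 100000 UMIs and 0.57 at 10% mitochondrial UMIs. In retina-like cells scinla (6.27) was -0.90 from 6000 UMIs above the mode and -2.33 from 10000 UMIs. pnoca, lower in the main setting, was 2.38 at Leiden resolution 1, 1.11 with a balanced graph, 1.1 from 6000 UMIs above the mode and 1.17 with no doublets removed. With every barcode, glulb was -0.039, gabrr2a -0.046 and cdo1 -0.079, and cdo1 was -0.065 with no background step.

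Of 24 genes named over the 3 compared classes, 24 kept their direction in most alternatives in which all could be measured. With every barcode, with no background step and without cells above 100000 UMIs 23 kept it. Fewer than 24 could be measured with 900 barcodes, with the background profile subtracted and without the top cell of each gene, and those measured kept it. For the rest, dependence on the top cell was not checked. After thinning only 2 could be measured and 1 kept it. muc5.2 (-2.36) was 0.41 with every barcode and 0.43 with no background step, and calb2a (-1.96) was 0.68 after thinning and 0.11 without cells above 100000 UMIs.

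Of 2179 list medians 1697 stayed close, 441 moved and 41 reversed. The fibrillar collagen median in neuron- and glia-like cells (-0.39) has no settled direction: it was 0.084 at Leiden resolution 1, 0.45 at resolution 3 and 0.33 with a balanced graph. It was 0.73 with no doublets removed, 0.74 with the highest doublet scores removed, 0.62 at 10% mitochondrial UMIs and 0.0059 with members of at least 100 UMIs. It was 0.65 with every barcode, 0.50 with no background step, 0.40 from 6000 UMIs above the mode, 0.70 from 10000 UMIs, 0.84 from 3 times the mode, 0.81 with 900 barcodes and 0.23 without cells above 100000 UMIs. In mesenchyme- and cartilage-like cells this list (0.23) was -0.18 with 900 barcodes and -0.092 from 10000 UMIs. Over all cells, the Mediator list was 0.030 with every barcode and 0.026 with no background step, and the proteasome list 0.0032 and 0.0039. Skeletal muscle (-0.18) was 0.22 and 0.24 there, 0.16 from 3 times the mode and 0.028 without top cells. Crystallins over all cells (-0.44) were 4.14 with the background profile subtracted. With TMM factors oxidative phosphorylation was -0.0047 and ribosomal proteins -0.033. Cholesterol synthesis (-0.14) was 0.12 after thinning, and the unfolded protein response (0.18) was -0.14 with classes weighted equally.

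Over the 3 compared classes lipid transport (0.30) was -0.14 at Leiden resolution 1, -0.10 with 900 barcodes and -0.62 with the background profile subtracted. Wnt targets (0.40) were -0.057 with members of at least 100 UMIs, splicing factors (-0.17) 0.00069 without cells above 100000 UMIs, and oxidative phosphorylation (0.06) -0.0057 over classes of 30 cells. The clock list was -0.042 in lens-like cells with at least 500 genes. In retina-like cells, synaptic genes (0.51) were -0.26 with every barcode and -0.035 with no background step, and crystallins (-0.75) were 1.67 and 1.11. Crystallins in neuron- and glia-like cells (-0.60) were 0.0084 from 10000 UMIs. The share of cells with G2 and M phase UMIs was -0.017 over all cells and 0.0051 in periderm-like cells when unthinned, where nearly all cells had such UMIs.

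Depth limits which genes were measured: 500 UMIs per cell left few genes measurable, and cells with less than 3000 UMIs above the mode were not separated from background. No paired analysis was possible because each group had 1 library.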

Other observations

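The test of glucocorticoid-response genes was chosen before its own result was seen, but after klf2a and fkbp5 had been found to be higher.

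In classes not compared gene by gene, klf2a was also higher in basal epidermis-like cells of the library labelled knockout, at 20.0 and 121 CPM (6.05-fold), and fzd10, a Wnt receptor, was lower, at 73.4 and 29.8 CPM (-1.30, -1.68 to -0.92). In ionocyte-like cells fkbp5 was counted at 10 and 472 UMIs (4.23, 3.34 to 5.30) and lpin1 at 48 and 739 UMIs (2.61, 2.19 to 3.06). In macrophage- and microglia-like cells, 15 and 43 in number, the apolipoprotein gene apoeb, which microglia express, was counted at 3 and 552 UMIs (6.20, 4.65 to 8.48), with 35.1% of the higher count in 1 cell.

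fkbp5, klf2a, lpin1 and per1a include genes that cortisol induces through the glucocorticoid receptor, so a stronger glucocorticoid response may underlie the pattern in which klf2a, fkbp5 and plekhs1 were higher in periderm-like cells. A list of 16 other glucocorticoid-response genes, of which 15 were measured, had a median log2 ratio of 0.74 over all cells (random lists -0.08 to 0.24; 13 members higher, 2 lower). The median was 1.36 in retina-like cells (10 higher, 0 lower), 0.45 in neuron- and glia-like cells (random lists -0.12 to 0.44) and 0.25 in periderm-like cells (-0.17 to 0.23), the last 2 only just above their ranges. Ratios over all cells also depend on the make-up of the library: glula was 1.05 over all cells. Within classes it was -0.10 in neuron- and glia-like, 0.19 in periderm-like and 1.96 in retina-like cells. The list was not recomputed with classes weighted equally. klf9 was counted at 8.64 and 26.5 CPM over all cells (1.62, 1.42 to 1.82), sgk1 at 645 and 1688 UMIs (1.18, 1.05 to 1.31) and tsc22d3 at 611 and 1315 UMIs (0.90, 0.76 to 1.04). In periderm-like cells zbtb16a (-1.71), zbtb16b (-1.59), mt2 (-1.47) and mao (-0.66) went the other way, as did sgk1 in neuron- and glia-like cells (-0.83, -1.37 to -0.29). The values are in the direction that the hypothesis predicts. Handling stress, genotype and the time of day or light at collection differ or may differ between the libraries and stay open as untested. per1a is also among the clock genes, so the glucocorticoid and clock patterns share a gene.

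polr2a had a log2 ratio of 1.76 in mesenchyme- and cartilage-like cells. slc2a1a, a glucose transporter, was counted at 4 and 48 UMIs in retina-like cells. The proteasome list had a median of -0.37 in retina-like cells, with 35 members lower and 0 higher.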
